A study of Homo sapiens with 12 samples.

How the data were processed

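RNA was measured in primary human cumulus cells, the follicle cells that surround the oocyte. Per the labels, the cells were plated in serum-free medium and kept for 48 h with no addition (control), with follicle stimulating hormone (FSH), with AEW, or with both (FSH+AEW). The series title speaks of an insulin-like growth factor 1 (IGF1) inhibitor, and AEW is taken here to be that compound; its dose was not given in the sources used here. Each of the 4 groups held 3 arrays, numbered 1 to 3 in the labels, 12 arrays in all. Total RNA was extracted with a column kit and labelled with biotin by in vitro transcription from the 3' end, per the labels' protocols, so each array carried 1 colour.

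The deposited values were log2 expression per probe set, and the authors made them with Partek and RMA, per the submitters' processing notes; no versions were given in the sources used here. RMA corrects the background, normalizes the arrays to a common distribution and summarises the probes of a probe set on the log2 scale. A common distribution hides any change in total RNA per cell, and RMA compresses small differences between dim probe sets. In the table the array medians ran from 4.68 to 4.78 and the values from 2.14 to 14.7, with no centring per probe set. Scanner files were not used here, so neither background calls nor scan dates were checked.

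The table held 49395 probe sets. Of these, 44988 were paired with 1 gene symbol, 1832 with several and 2569 with none in the annotation used here, and the other 6 were the array's own control probe sets for ACTB and GAPDH, used only for RNA quality. The array's 102 control probe sets, most of them among those with no gene, entered no gene test. Symbols were updated through Entrez identifiers to the RefSeq names of GRCh38.p14, which matched 18112 of 18132 genes. No genome build is named for these values, and no coordinates are given. For each gene the probe set with the highest mean over the 12 arrays was used; 11734 genes had more than 1. Probe sets with several genes or no gene were left out of the gene tests. Probe sets of the same gene were compared over 348 named values. None of these had probe sets called in opposite directions with the replicate block, although in 85 the estimates differed in sign.

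Gene tests used lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 4 group means over all 12 arrays in 1 fit, no block, no filter on dim probe sets and no fold threshold. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over 18132 genes, two-sided. The 5 comparisons were FSH with control, AEW with control, FSH+AEW with FSH, FSH+AEW with AEW, and the interaction, which is the FSH effect with AEW minus the FSH effect without it. A total of 20 gene lists, 14 of pathways and 6 of cell type markers, were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over all 100 tests of 20 lists in 5 comparisons. The lists held 373 genes, of which 349 were measured; the others, IGF2 among them, were not analysed here. In the text a list's spread is the SD of the median differences within the 3 replicate numbers. It lies around the mean of these 3 medians, not around the median of the group differences printed before it, and that mean is also given where the 2 lie more than 1 SD apart. Differences of genes are log2 values with their SE from the fit.

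The share of the FSH response retained with AEW was measured without selecting and measuring genes on the same arrays. Genes called for FSH against control in 2 replicate numbers were taken, or the 100 genes with the smallest p where fewer than 10 were called. The median FSH effects with and without AEW were then compared in the number left out. The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names, per comparison, the 5 largest rises and falls among genes that passed with non-overlapping arrays, places left empty being filled by the smallest p. It also names up to 4 members per list in order of p, and a panel of STAR, CYP11A1, HSD3B2, CYP19A1, FSHR, LHCGR, INHA, INHBA, IGF1R, IGF2, IRS2 and HAS2.

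The replicate numbers were checked for pairing before any calls were compared. After subtraction of group means, the 18 pairs of arrays with the same number correlated across genes at r = 0.441 to 0.700, against -0.599 to 0.138 for arrays of another number and group, and 12 of 12 arrays correlated best with their own number. The numbers therefore pair the samples. The pairing comes from the data, since the labels do not say what a number stands for. Values with the replicate number as a fixed block are given beside the counts of genes, the lists called by camera and the named genes whose calls they change. The labels do not state separate donors or cultures either, so p-values measure only the spread between these samples, which may be technical. The number of arrays, 3 per group, limits the precision.

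The fits were tested on simulated data with 200 changed genes among 18132 in 10 draws. For FSH against control, 65.6% of changes of 1 log2 unit and 95.0% of changes of 2 were recovered without the block, and 89.5% and 99.3% with it. For the interaction the shares were 29.0% and 86.1% without the block, and 65.7% and 97.2% with it. The simulated noise followed the model of the block, so the gain with the block was built in. Of the genes called for FSH against control, 0.315% on average were false without the block and 5.34% with it. In simulations of the FSH comparison camera called 10 of 10 lists shifted by 0.5 and 1 of 200 unshifted lists, at an unadjusted p under 0.05. These lists were random genes with noise drawn separately for each gene. The 1 of 200 therefore does not give the error rate for lists of genes that vary together. A true retained share of 60% was estimated at 58.7% ± 1.01 (SD over 10 draws). Every changed gene had the same share there, so a bias from choosing genes by their effect without AEW could not show. The alternatives were the block as a fixed or random term, array weights, other rules for probe sets, a filter on the third of genes with the lowest mean, repeated quantile normalization, median centring, a 2-fold threshold, fits on the arrays of 2 groups, and leaving out each array and each replicate number.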

Results

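Expression was compared in human cumulus cells after 48 h in serum-free medium, in a 2 by 2 design of FSH and AEW with 3 arrays in each of 4 groups. FSH is the pituitary hormone that drives granulosa and cumulus cell differentiation, and IGF1 signalling is known to act beside it. Within groups, arrays correlated at r = 0.983 to 0.990 for control, 0.975 to 0.991 for FSH, 0.990 to 0.992 for AEW and 0.981 to 0.988 for FSH+AEW, across probe sets. The first 2 principal components held 35.4% and 27.1% of the variance. The 3' minus 5' difference of the ACTB control probe sets, a measure of RNA integrity, was 1.25 ± 0.11 in control, 1.42 ± 0.16 with FSH, 1.20 ± 0.21 with AEW and 1.64 ± 0.11 with FSH+AEW (log2, SD, n = 3). For GAPDH it was 0.28 ± 0.05, 0.21 ± 0.02, 0.29 ± 0.10 and 0.35 ± 0.09 in the same order.

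The first comparison asked what FSH alone changed. Genes of steroid hormone synthesis were among those that rose with FSH. STAR, which carries cholesterol into mitochondria, went from 9.33 ± 0.68 to 11.71 ± 0.25 (log2, SD, n = 3), a 5.22-fold rise, and CYP11A1, which cleaves the cholesterol side chain, rose 2.65-fold. INHA, the inhibin alpha subunit, rose 6.11-fold. TAGLN, an actin-binding protein of smooth muscle, went from 9.46 ± 0.55 to 6.40 ± 0.95 and was 8.36-fold lower. HAS2, which makes the hyaluronan of the cumulus matrix, was 3.14-fold lower. In all, 102 genes rose and 123 fell of 18132, by limma's test with Benjamini-Hochberg adjustment. With the replicate block 701 rose and 886 fell, and these held 225 of the 225. Array weights gave 724 genes, the number as a random effect 1135, a 2-fold threshold 130 and a fit on the 6 arrays of this comparison 12.

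The largest rises among genes that passed without the block were those of MRO, by 4.78 ± 0.35 (log2, SE, n = 3), XYLT1, which starts glycosaminoglycan chains, by 3.32 ± 0.47, the galectin LGALS12 by 3.15 ± 0.26, the chemokine CCL20 by 2.96 ± 0.45, and HSD11B1, which turns cortisone into cortisol, by 2.86 ± 0.33. Their adjusted p ran from 0.000301 for MRO to 0.0115 for CCL20 in limma's test with Benjamini-Hochberg adjustment. The largest falls among these genes were those of TNFRSF11B, the decoy receptor osteoprotegerin (-3.39 ± 0.73), TAGLN (-3.06 ± 0.55), the secreted WNT antagonist SFRP4 (-2.89 ± 0.38), the cGMP phosphodiesterase PDE5A (-2.70 ± 0.31) and ALKAL2 (-2.52 ± 0.42). For these, limma's adjusted p ran from 0.00321 for PDE5A to 0.0491 for TNFRSF11B.

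Of 18 measured steroidogenesis genes, 8 rose and 0 fell, and 13 rose and 1 fell adjusted over the list alone and also with the block. FDX1, the electron donor of CYP11A1, rose by 1.74 ± 0.22, STAR by 2.38 ± 0.32, CYP11A1 by 1.41 ± 0.17 and HSD11B1 as above. Aromatase, CYP19A1, had a difference of 2.36 ± 0.57 (adjusted p = 0.0825 in limma's test), and HSD3B2 one of 2.58 ± 0.82 (adjusted p = 0.218); with the block their adjusted p were 0.000582 and 0.00520. The list median was 1.38 ± 0.12 (SD of 3 numbers, whose mean was 1.15), with camera adjusted p = 7.97e-14 at the preset and 0.0643 with an estimated correlation.

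Cholesterol genes moved with them. Of 19 members 13 rose and 0 fell, 17 and 0 adjusted over the list alone, with a median of 0.92 ± 0.14 (camera adjusted p = 5.23e-29, and 0.0643 with an estimated correlation). HMGCS1, an early enzyme of the mevalonate pathway, rose by 1.77 ± 0.22, EBP by 1.51 ± 0.15, DHCR7, the last step to cholesterol, 2.82-fold and MSMO1 by 1.44 ± 0.14. Of 15 fatty acid synthesis genes 5 rose and 0 fell, 9 and 0 adjusted over the list alone, at a median of 0.50 ± 0.16 (camera adjusted p = 2.79e-10, and 0.0643 with an estimated correlation). With the block 9 rose. The desaturases FADS1 and SCD rose by 1.05 ± 0.14 and 0.89 ± 0.14.

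In the granulosa list 1 of 22 genes rose, INHA by 2.61 ± 0.42, and 4 rose adjusted over the list alone; with the block 7 rose and 1 fell. Its median was 0.13 ± 0.03 (mean of the numbers 0.17, camera adjusted p = 0.0271, and 0.123 with an estimated correlation). LHCGR, the luteinizing hormone receptor, was bright at 9.96 in control, with a difference of 0.76 ± 0.31 (adjusted p = 0.367 in limma's test, 0.0394 with the block). FSHR was near the lowest values of the arrays at 3.47 in control and 3.28 with FSH. Of 16 cumulus expansion genes 1 rose and 1 fell, 1 and 3 adjusted over the list alone: the epidermal growth factor family member EREG rose by 1.76 ± 0.29 and HAS2 changed (-1.65 ± 0.28). With the block 2 rose and 8 fell, among them GREM1 at -1.74 ± 0.23, and camera gave an adjusted p of 0.124 without the block and 0.00835 with it, a call lost at adjusted p = 0.212 with the block and an estimated correlation.

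Of 23 extracellular matrix and contractile genes 0 rose and 3 fell, 1 and 12 adjusted over the list alone, and 1 and 14 with the block. TAGLN, tropomyosin TPM1 (-1.97 ± 0.43) and thrombospondin THBS1 (-1.66 ± 0.29) fell, and the collagen gene COL1A2 fell with the block (-2.19 ± 0.23). The median was -0.67 ± 0.17 (camera adjusted p = 2.57e-07, and 0.110 with an estimated correlation). The ACTB 3' control probe set moved with them, from 13.30 ± 0.11 in control to 12.80 ± 0.10 with FSH (log2, SD, n = 3).

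Of 21 glycolysis and hypoxia genes 1 rose, the aldolase ALDOC by 1.17 ± 0.22, the same number adjusted over the list alone, and 6 rose with the block, including VEGFA at 1.30 ± 0.17. The list median was 0.45 ± 0.35 (camera adjusted p = 3.00e-06, and 0.494 with an estimated correlation). FOXO targets had 1 fall among 27, GADD45A at -1.87 ± 0.29, 2 rises and 5 falls adjusted over the list alone, and 2 and 7 with the block (median -0.07 ± 0.03, mean of the numbers -0.15, camera adjusted p = 0.0220, and 0.646 with an estimated correlation). In the ATF4 and amino acid list 2 of 23 fell, ATF3 at -2.27 ± 0.39 and NUPR1 at -0.87 ± 0.18, with 2 rises and 2 falls adjusted over the list alone and 3 and 5 with the block (median -0.35 ± 0.46, camera adjusted p = 0.0481, and 0.920 with an estimated correlation). ATF3 and NUPR1 are stress-induced regulators rather than amino acid enzymes. AKAP12 fell (-1.28 ± 0.24) in the cAMP list and MCM7 (-0.71 ± 0.13) in the cell cycle list, in lists that camera did not call. The count of 225 was 74, 70, 46 and 149 without control replicate 1, control replicate 2, FSH replicate 3 and AEW replicate 1, and 41, 97 and 4 without replicate numbers 1, 2 and 3. The blocked count of 1587 was 946, 969 and 922 without control replicate 1, control replicate 2 and FSH replicate 3, and 714 and 763 without numbers 1 and 3.

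**Figure D1:**
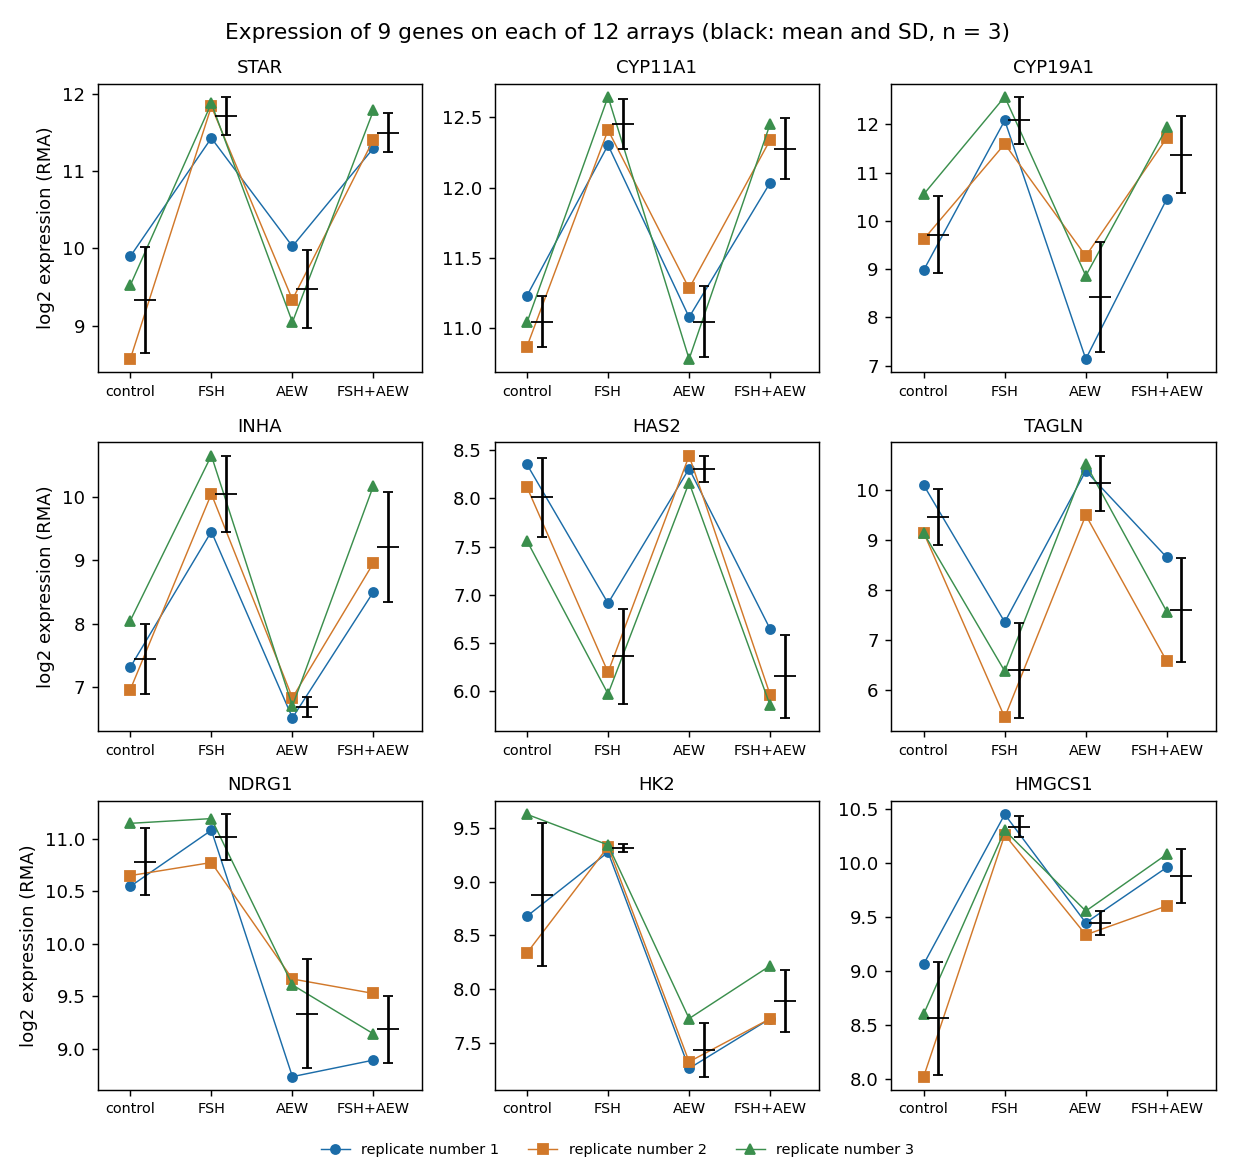
Log2 expression (RMA, y axis) of 9 genes by group (x axis), with 1 marker per array, lines joining arrays of the same replicate number, and black bars for the mean and SD of n = 3. STAR and INHA lie higher and HAS2 and TAGLN lower on the FSH arrays than on the control arrays, and HK2 averages 7.44 with AEW against 8.88 in control.

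The second comparison asked what AEW changed in cells without FSH. With the replicate number as a block, HK2, the hexokinase that opens glycolysis, fell 2.72-fold from 8.88 ± 0.67 to 7.44 ± 0.25 (log2, SD, n = 3), and NDRG1, a hypoxia-induced gene, fell 2.72-fold. PAPPA, the protease that frees IGF from its binding proteins, rose 3.37-fold with the block. STAR differed by 0.14 (95% interval without the block, not adjusted over genes, -0.57 to 0.85), CYP11A1 by 0.00 (-0.36 to 0.36) and CYP19A1 by -1.29 (-2.54 to -0.04). None of these passed the adjusted test with or without the block. CYP19A1 went from 8.98 to 7.14, 9.62 to 9.27 and 10.55 to 8.86 in numbers 1, 2 and 3. With the block and adjusted over the list alone, 2 of 18 steroidogenesis genes rose and 4 fell. No gene passed limma's test with Benjamini-Hochberg adjustment, with 838 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.288. With the replicate block 374 genes passed, of which 109 rose and 265 fell, and 2265 had an unadjusted p under 0.05. Array weights gave 3 genes and the number as a random effect 77.

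The genes with the smallest p did not pass without the block. On the higher side these were FEZ1 at 0.77 ± 0.13 (log2, SE, n = 3), SRPX2 at 0.83 ± 0.15, SQOR at 0.68 ± 0.12, LYSMD2 at 0.76 ± 0.14 and ERICH5 at 0.95 ± 0.18. On the lower side they were the antiproliferative gene BTG1 at -0.95 ± 0.14, ANK3 at -1.38 ± 0.24, NDRG1 at -1.44 ± 0.26, HK2 at -1.44 ± 0.27 and the protease inhibitor SERPINE2 at -0.80 ± 0.15. Their adjusted p in limma's test were 0.288 for BTG1 and 0.406 for the others, against 0.00164 for BTG1 and at most 0.0144 (LYSMD2) with the block.

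Among the lists, glycolysis and hypoxia genes lay lower with AEW, at a median of -0.38 ± 0.15 (camera adjusted p = 9.64e-09, and 0.396 with an estimated correlation). None of 21 passed over all genes, 2 fell adjusted over the list alone, and 3 fell with the block, ALDOC (-0.66 ± 0.13) beside NDRG1 and HK2. Cholesterol genes lay higher, at 0.44 ± 0.19 (camera adjusted p = 5.17e-13, and 0.110 with an estimated correlation); 9 of 19 rose adjusted over the list alone and 7 with the block, including ACAT2 at 0.94 ± 0.14 and HMGCS1 at 0.88 ± 0.16. The granulosa list lay lower at -0.21 ± 0.13 (camera adjusted p = 0.000673, and 0.0643 with an estimated correlation), with 2 falls adjusted over the list alone. With the block SERPINE2 fell and the activin-binding protein FST rose by 1.23 ± 0.20. FOXO targets lay lower at -0.21 ± 0.15 (camera adjusted p = 5.04e-05, and 0.338 with an estimated correlation), where TXNIP, an inhibitor of glucose uptake, fell (-1.07 ± 0.16) with the block. ATF4 genes lay higher at 0.23 ± 0.07 (camera adjusted p = 0.00174, and 0.646 with an estimated correlation), and 1 of 23 rose with the block. In the cell cycle list, not called by camera, the mitotic kinase BUB1 fell (-1.74 ± 0.13) with the block. The blocked count of 374 was 125 and 72 without control replicates 1 and 3, 170, 236 and 99 without AEW replicates 1, 2 and 3, and 68 and 41 without numbers 1 and 3.

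The third comparison asked what AEW changed in cells given FSH. The glycolysis and hypoxia list had a mean difference of -0.94; 0 rose and 0 fell of its 21 genes without the block, and camera's call was lost at adjusted p = 0.110 with an estimated correlation. The 3' bias of ACTB and GAPDH was also higher in FSH+AEW, at 1.64 ± 0.11 and 0.35 ± 0.09, than in FSH, at 1.42 ± 0.16 and 0.21 ± 0.02 (log2, SD, n = 3). With these as covariates, 1 at a time, the list mean was -0.74 ± 0.20 (ACTB) and -0.44 ± 0.14 (GAPDH, SE). With the block NDRG1 fell 3.55-fold from 11.01 ± 0.22 to 9.19 ± 0.32 (log2, SD, n = 3), HK2 2.68-fold, ALDOC 2.24-fold and P4HA1, a collagen prolyl hydroxylase, 1.88-fold. COL10A1, collagen X, rose 4.74-fold with the block. The steroidogenic genes STAR (-0.22 ± 0.32), CYP11A1 (-0.18 ± 0.17), HSD3B2 (-0.46 ± 0.82) and CYP19A1 (-0.71 ± 0.57) did not pass with or without it. Here too no gene passed limma's test without the block and with equal array weights, with 1101 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0602; with the block 185 genes rose and 366 fell, with 2581 at an unadjusted p under 0.05. With array weights and no block 882 rose and 1075 fell, and the number as a random effect gave 238.

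Of 21 glycolysis and hypoxia genes none passed over all genes, 17 fell adjusted over the list alone and 15 fell with the block. Camera's adjusted p was 4.94e-22, and 0.110 with an estimated correlation, and the medians within numbers 1, 2 and 3 were -1.33, -0.48 and -1.12. Other genes with the smallest p were TFPI2 (0.93 ± 0.14), CPE (1.32 ± 0.21), FEZ1 (0.85 ± 0.13) and PAPLN (1.56 ± 0.25) on the higher side with COL10A1 (2.24 ± 0.29), and DDX41 (-1.11 ± 0.15), ALDH18A1 (-0.73 ± 0.10), MTCP1 (-1.45 ± 0.21) and SSPN (-1.03 ± 0.15) on the lower side with NDRG1 (-1.83 ± 0.26). Without the block limma's adjusted p ran from 0.0602 (NDRG1) to 0.0852 (PAPLN), and with it the highest was 0.00257, for TFPI2.

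IGF system genes went both ways, and camera did not call the list. With the block 3 rose and 2 fell: the binding protein IGFBP1 rose by 2.66 ± 0.47, PAPPA by 1.41 ± 0.28 and the docking protein IRS1 by 0.49 ± 0.10, while STC1, an inhibitor of PAPPA, fell (-1.90 ± 0.37). Of FOXO targets, another list that camera did not call, TXNIP fell (-1.51 ± 0.16) and CCNG2 (-0.61 ± 0.10), and KLF15 and DEPP1 rose by 0.63 ± 0.15 and 1.57 ± 0.39 with the block, among 2 rises and 3 falls. BUB1 (-1.65 ± 0.13), thymidylate synthase TYMS (-1.07 ± 0.16) and CDK1 (-0.98 ± 0.19) fell with the block in a cell cycle list that camera did not call. Camera called the steroidogenesis list at a median of -0.25 ± 0.09 (adjusted p = 0.00113, and 0.308 with an estimated correlation), the granulosa list at -0.27 ± 0.09 (adjusted p = 0.000624, and 0.0643 with an estimated correlation) and the fatty acid list at -0.12 ± 0.05 (adjusted p = 0.0257, and 0.494 with an estimated correlation). Adjusted over the list alone, 0, 1 and 0 of their members fell. Those that fell with the block were CYP17A1 (-1.58 ± 0.39) in the first, CCND2 (-0.52 ± 0.12) in the second, and SCD (-0.48 ± 0.11) and SREBF1 (-0.53 ± 0.13) in the third, and 1 granulosa gene rose. The blocked count of 551 was 325 and 230 without FSH replicates 1 and 3, 236, 318 and 320 without FSH+AEW replicates 1, 2 and 3, and 130 and 157 without numbers 1 and 3.

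The fourth comparison asked what FSH changed in cells given AEW. Steroidogenic genes were among those that rose: STAR went from 9.47 ± 0.50 to 11.50 ± 0.26 (log2, SD, n = 3), a 4.07-fold rise, CYP11A1 rose 2.34-fold and HSD3B1, which makes progesterone from pregnenolone, 6.33-fold. INHA rose 5.78-fold. HAS2 fell from 8.31 ± 0.14 to 6.15 ± 0.43, a 4.45-fold difference. By limma's test with Benjamini-Hochberg adjustment 42 genes rose and 25 fell, and with the replicate block 561 rose and 665 fell, including 67 of the 67. Array weights gave 581 genes, the number as a random effect 825 and a test of every probe set 102. The ACTB 3' minus 5' difference was higher in FSH+AEW, at 1.64 ± 0.11, than in AEW, at 1.20 ± 0.21, and that of GAPDH was 0.35 ± 0.09 against 0.29 ± 0.10 (log2, SD, n = 3).

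Among genes that passed without the block, the largest rises were those of MRO by 4.26 ± 0.35 (log2, SE, n = 3), XYLT1 by 3.51 ± 0.47, LGALS12 by 2.99 ± 0.26, HSD3B1 by 2.66 ± 0.46 and INHA by 2.53 ± 0.42. The largest falls among the same genes were those of the smooth muscle actin ACTG2 (-2.26 ± 0.41), HAS2 (-2.16 ± 0.28), SFRP4 (-2.11 ± 0.38), the transcription factor ETS1 (-2.00 ± 0.29) and the formin DIAPH3 (-1.89 ± 0.27). Limma's adjusted p for these 10 genes ran from 0.00106 for MRO to 0.0457 for SFRP4. When every probe set was tested, ETS1 passed on 1 of its 3 probe sets, with and without the block (range -2.00 to -0.09).

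Of 18 steroidogenesis genes 7 rose, 10 rose and 1 fell adjusted over the list alone, 10 rose and 2 fell with the block, and the median was 0.98 ± 0.20 (camera adjusted p = 2.79e-10, and 0.0643 with an estimated correlation). FDX1 rose by 1.61 ± 0.22 and HSD11B1 by 2.13 ± 0.33, while CYP19A1 had a difference of 2.95 ± 0.57 (adjusted p = 0.0532 in limma's test, 0.000220 with the block). Of 19 cholesterol genes 2 rose, DHCR7 by 0.81 ± 0.15 and EBP by 0.84 ± 0.15, with 14 rises adjusted over the list alone and 13 with the block. Their median was 0.55 ± 0.16 (camera adjusted p = 5.53e-16, and 0.105 with an estimated correlation). The fatty acid list lay higher at 0.27 ± 0.04 (mean of the numbers 0.37, camera adjusted p = 0.000209, and 0.209 with an estimated correlation), with 5 rises adjusted over the list alone and 6 with the block, and the granulosa list at 0.13 ± 0.07 (camera adjusted p = 0.0248, and 0.120 with an estimated correlation), with 5 rises and 1 fall adjusted over the list alone and 7 and 3 with the block.

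Matrix and contractile genes lay lower at -0.60 ± 0.26 (camera adjusted p = 6.68e-07, and 0.110 with an estimated correlation). None of 23 passed over all genes, 7 fell adjusted over the list alone and 10 fell with the block, TAGLN (-2.54 ± 0.24), TPM1 (-1.64 ± 0.20) and COL1A2 (-1.80 ± 0.23). The ATF4 list lay lower at -0.36 ± 0.23 (camera adjusted p = 0.000100, and 0.494 with an estimated correlation), where 2 rose and 6 fell with the block, the mitochondrial folate enzyme MTHFD2 (-1.08 ± 0.21). Lower medians were also called for the cell cycle list, -0.13 ± 0.11 (camera adjusted p = 0.0202, and 0.110 with an estimated correlation), and for epithelial markers, -0.20 ± 0.05 (camera adjusted p = 0.0448, and 0.414 with an estimated correlation); cyclin D1, CCND1, fell (-1.60 ± 0.28) and the keratins KRT8 (-1.20 ± 0.23) and KRT18 (-1.25 ± 0.21) fell with the block, in lists with 1 rise and 2 falls, and 0 rises and 3 falls. With every probe set tested, CCND1 passed with the block on 1 of its 4 probe sets (range -1.60 to -0.02). Among cumulus expansion genes 3 rose and 8 fell with the block, the proteoglycan VCAN (-1.24 ± 0.15), and camera's adjusted p was 0.109 without the block and 0.00673 with it, a call lost at adjusted p = 0.212 with the block and an estimated correlation. GADD45A fell (-1.59 ± 0.29), the 1 call without the block among 27 FOXO targets, a list that camera did not call; 3 rose and 2 fell with the block. The count of 67 was 18, 7 and 3 without AEW replicates 1, 2 and 3, 119, 3 and 3 without FSH+AEW replicates 1, 2 and 3, 44 without control replicate 1, 41 without FSH replicate 3, and 26, 2 and 5 without the numbers. The blocked count of 1226 was 817 and 673 without AEW replicates 2 and 3, 748 without FSH+AEW replicate 2, and 632 and 476 without numbers 1 and 3.

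**Figure D2:**
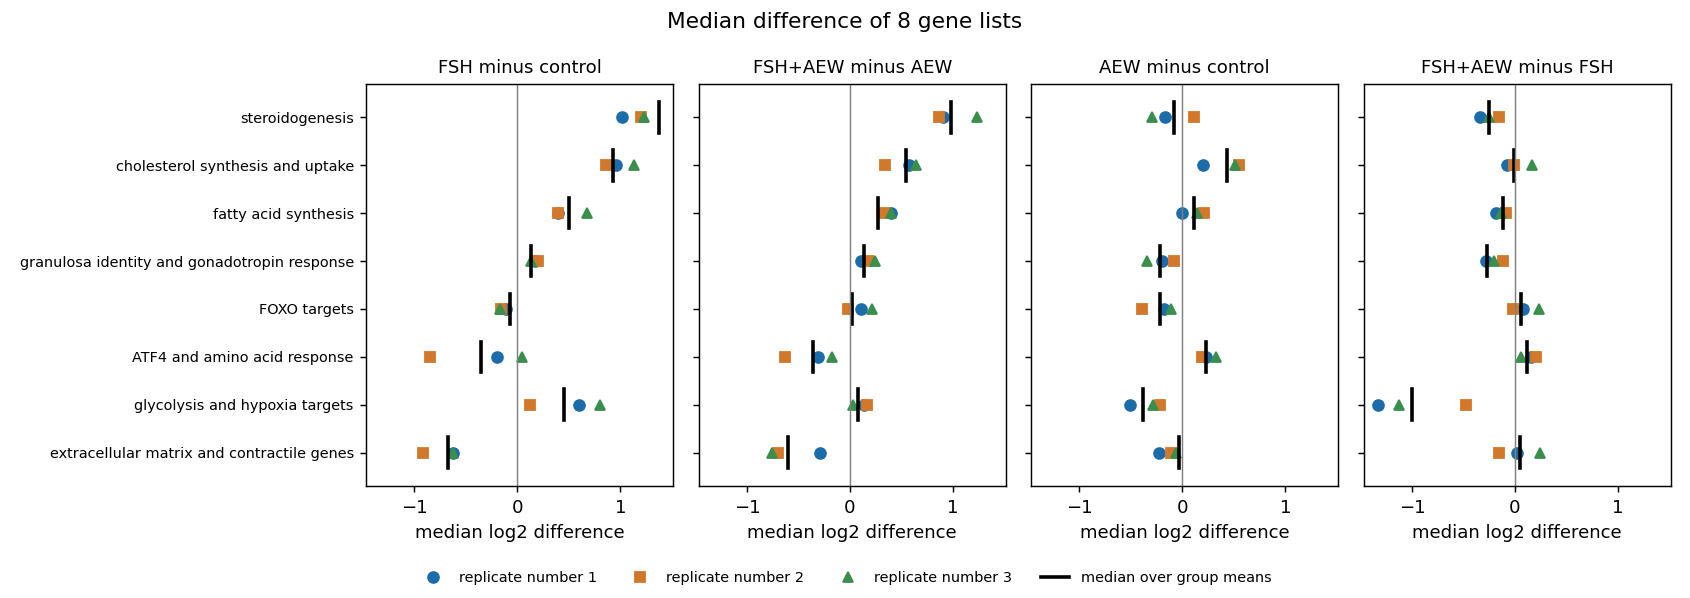
Median log2 difference (x axis) over the measured genes of 8 lists (rows) in 4 comparisons (panels), with 1 marker per replicate number and a black bar for the median of the differences between group means. Steroidogenesis and cholesterol medians lie above 0 for all 3 numbers in both FSH comparisons, and the glycolysis and hypoxia markers lie at -1.33, -0.48 and -1.12 in FSH+AEW minus FSH.

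The fifth comparison asked whether the FSH effect differed with and without AEW. The cholesterol, fatty acid, and glycolysis and hypoxia lists had a smaller FSH effect with AEW, and FOXO targets a more positive one, by camera at the preset correlation. These calls were lost at adjusted p = 0.110, 0.238, 0.494 and 0.449 with an estimated correlation, in that order. For cholesterol genes the median interaction was -0.41 ± 0.11, with HMGCS1 at -1.34 ± 0.31 and INSIG1 at -0.91 ± 0.26. No single gene passed limma's test of the interaction, with 304 genes at an unadjusted p under 0.05, and none passed with the replicate block, with 1070 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.194. Without the block, the interaction was -0.36 for STAR (95% interval -1.36 to 0.64) and -0.18 for CYP11A1 (-0.69 to 0.34). In the same fit it was 0.58 for CYP19A1 (-1.18 to 2.35) and -0.08 for INHA (-1.36 to 1.20).

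Camera's adjusted p for the interaction was 5.74e-13 for cholesterol genes, and 0.110 with an estimated correlation; 5 of 19 had a lower effect adjusted over the list alone. For glycolysis and hypoxia genes the median was -0.51 ± 0.24 (camera adjusted p = 3.18e-06, and 0.494 with an estimated correlation), for fatty acid synthesis -0.28 ± 0.10 (0.000456, and adjusted p = 0.238 with an estimated correlation) and for FOXO targets 0.28 ± 0.11 (0.000735, and adjusted p = 0.449 with an estimated correlation). FSH+AEW, 1 of the 4 groups in these differences, had the highest 3' minus 5' differences, 1.64 ± 0.11 for ACTB and 0.35 ± 0.09 for GAPDH (log2, SD, n = 3). With GAPDH's as a covariate the glycolysis and hypoxia mean in FSH+AEW against FSH was -0.44 ± 0.14, against -0.94 ± 0.16 (SE) without it; the interaction was not fitted with a covariate. KLF15, a member of the FOXO list, was at 0.64 ± 0.22 and did not pass. The steroidogenesis list was called at -0.17 ± 0.16 (camera adjusted p = 0.0481, and 0.582 with an estimated correlation) and lost its call with the replicate block (adjusted p = 0.0824). Among single genes the smallest p went to TFPI2 (1.06 ± 0.20), ASAP3 (0.71 ± 0.15), ACACB (0.94 ± 0.22), DNAH2 (0.92 ± 0.23) and CITED4 (0.91 ± 0.24) on the positive side, and to HMGCS1, GPR160 (-0.92 ± 0.23), ANKRD16 (-0.73 ± 0.19), PPP1R3C (-1.57 ± 0.40) and CDK5R2 (-0.60 ± 0.16) on the negative side.

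FSH effects without and with AEW, which share no array, correlated at r = 0.747 across genes, which are not independent replicates. Of the 225 genes called without AEW, 223 had the same sign with AEW, and 50 were called in both, against 0.406 for independent lists. With the block 769 genes were called in both in the same direction and 1 in opposite directions, against 54.2. AEW effects without and with FSH correlated at r = 0.544 across genes, and with the block 129 genes were called in both in the same direction and 0 in opposite directions, against 6.46. The share of the FSH response retained with AEW was 63.6%, 57.7% and 91.8% with replicate numbers 1, 2 and 3 left out of the gene selection, over 41, 97 and 100 genes, and 71.0% ± 18.2 on average (SD, n = 3). The genes were chosen by their FSH effect without AEW, which favours genes whose effect is larger there. The reverse choice, by the effect with AEW, was not made, so the share does not show a weaker response with AEW. Over all genes the SD of the FSH effects was 0.331 without AEW and 0.304 with it.

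**Figure D3:**
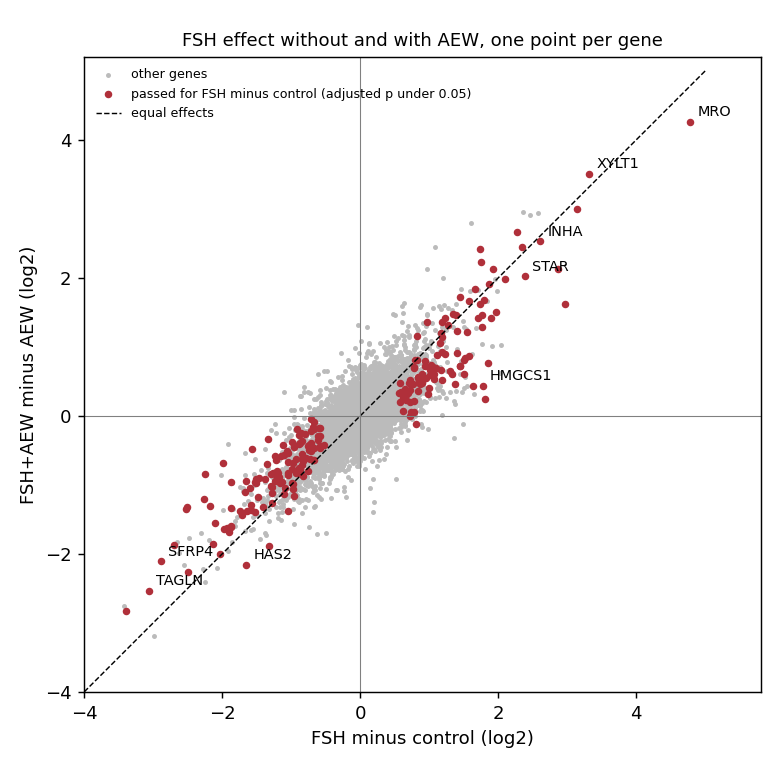
Log2 difference FSH+AEW minus AEW (y axis) against FSH minus control (x axis), with 1 point per gene, genes that passed for FSH minus control in red and a dashed line of equal effects. Red points were selected on the x axis, and 223 of the 225 have the same sign on both axes.

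Among 6 lists of other cell types' markers, the epithelial list was called in FSH+AEW against AEW, as given above, and with the block also in FSH against control (median -0.16 ± 0.09, camera adjusted p = 0.109 without the block and 0.0379 with it, and adjusted p = 0.319 with the block and an estimated correlation), where 1 rose and 3 fell with the block. Camera called none of the 5 comparisons for leukocyte (smallest adjusted p = 0.916), endothelial (0.206), theca (0.697), oocyte (0.244) or erythrocyte markers (0.756). The leukocyte marker PTPRC was at 2.87 and the oocyte growth factor GDF9 at 3.10 in control, near the lowest values of the arrays, while HLA-DRA was bright at 11.95. With the block 1 of 18 leukocyte markers rose and 1 fell with FSH, the macrophage genes CD68 at 0.63 ± 0.15 and CD14 at -0.95 ± 0.23, and CD14 fell with AEW (-1.05 ± 0.23). Of 7 theca markers 2 rose with FSH and the block, CYP17A1 at 1.47 ± 0.39 among them. The pathway lists of the cAMP response (smallest adjusted p = 0.150), the IGF system (0.805), apoptosis (0.150) and cytokines (0.394) were not called by camera in any comparison. With the block and FSH against control, 3 rose and 1 fell in the cAMP list, 0 and 4 in the IGF list, 0 and 2 in the apoptosis list, and 3 and 5 in the cytokine list. Among these RGS2, a regulator of G protein signalling, rose by 1.08 ± 0.22, the interferon-induced IFIT1 and IFIT3 rose by 1.18 ± 0.24 and 0.51 ± 0.14, the proapoptotic PMAIP1 fell (-1.97 ± 0.16), IRS2 fell (-0.92 ± 0.20) and the cytokine LIF fell (-0.90 ± 0.12). IGF1R differed by 0.15 ± 0.29 with FSH and by -0.30 ± 0.29 with AEW, and INHBA by 0.30 ± 0.22 and 0.08 ± 0.22, none of which passed. In FSH+AEW against AEW, IGF1R rose by 0.70 ± 0.16 and the insulin receptor INSR by 1.30 ± 0.21 with the block (limma adjusted p = 0.0179 and 0.00224), while without it neither passed (0.453 and 0.395). With every probe set tested, IGF1R passed with the block on 3 of its 7 probe sets (range -0.12 to 1.08).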

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

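All tests of explanations in this part were set before their results were seen, except the comparison with random lists and the fit with the GAPDH covariate. Camera's test of the interaction singled out 5 gene lists whose FSH effect differed with and without AEW. Their median interactions were -0.17 for steroidogenesis, -0.41 for cholesterol synthesis and uptake, -0.28 for fatty acid synthesis, 0.28 for FOXO targets and -0.51 for glycolysis and hypoxia targets, and none held with an estimated correlation. A signal also appeared in probe sets outside the gene tests. Of 4305 probe sets paired with several genes or with none, control probe sets left out, 37 passed for FSH against control, 19 of them higher. With the replicate block 248 passed. This was limma's test with Benjamini-Hochberg adjustment over all probe sets but the controls. The share was not larger than among the tested genes, where 225 of 18132 passed without the block and 1587 with it. Probe sets of several genes can also report genes already tested.

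The smaller FSH effect on cholesterol genes with AEW was set against 2 technical explanations. Bright probe sets near the top of the range, whose highest value was 14.7, would leave no interaction among dimmer members. Of the 19 members 18 had a mean under 11, with a median of -0.40 ± 0.11 (SD of 3 numbers). These are nearly the whole list, so their median had to lie close to that of the list. What speaks against this explanation is only that most members lie below that mark. A single array is also argued against, since the highest median over the 12 left-out arrays was -0.35, against -0.41 with all arrays. The interaction is also the AEW effect with FSH minus the AEW effect without it. These genes lay higher with AEW alone, by a median of 0.44, while FSH+AEW differed from FSH by a median of -0.01. For the list median, the smaller FSH effect thus lay in a higher level with AEW alone, not in a lower level with both. This does not hold for every member. In FSH+AEW against FSH 8 of 19 lay above 0, and 0 rose and 1 fell with the block. HMGCS1 was at 9.96, 9.60 and 10.08 with both, against 10.45, 10.26 and 10.30 with FSH, in numbers 1, 2 and 3. Whether FSH saturates the pathway was not tested. The interaction's call rests on camera's preset correlation (adjusted p = 0.110 with an estimated one).

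Lower glycolysis and hypoxia genes in FSH+AEW than in FSH may have a technical source, because the 3' bias of the RNA was also higher there. With the ACTB 3' minus 5' difference as a covariate beside group and number, the list mean was -0.74 ± 0.20 (SE), against -0.94 ± 0.16 without it, which met the bound of -0.5 set beforehand for excluding 3' bias. The same fit with GAPDH gave -0.44 ± 0.14, above that bound, so ACTB alone did not settle it. RNA quality cannot be told apart from the treatment for at least part of the difference, and GAPDH is itself a glycolytic gene. The ACTB difference was also higher in FSH+AEW (1.64 ± 0.11) than in AEW (1.20 ± 0.21, SD), yet the list median there was 0.08 ± 0.07. Those groups also differ in FSH. In AEW against control (1.25 ± 0.11) the ACTB difference was not higher, yet the list median was -0.38 ± 0.15. For ACTB a higher 3' bias thus did not go with a lower list in every comparison. The GAPDH difference ran closer to the reverse of the list. It was lower with FSH (0.21 ± 0.02) than in control (0.28 ± 0.05), where the list median was 0.45 ± 0.35. It was higher in FSH+AEW (0.35 ± 0.09) than in FSH, where the list was lower. In FSH+AEW against AEW (0.29 ± 0.10) it was also higher, without a lower list, and AEW was near control, with a lower list. The lowest median of 10000 expression-matched random lists was -0.20, so no shift of all genes of this brightness was seen that would be the whole cause. The common distribution of the arrays leaves little room for such a shift, so this outcome was largely fixed in advance. It does not test the list's own call. HIF targets outside the fixed list, chosen after the main results, had a median of -0.66 (camera adjusted p = 4.29e-09, a call lost at adjusted p = 0.122 with an estimated correlation). They were measured on the same arrays and not fitted with a covariate, so they cannot separate a wider response from RNA quality. Lower activity of hypoxia-inducible factors is only a hypothesis, since oxygen, cell number and IGF1 signalling were not measured.

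Other splits of the arrays were counted for each result. For each pairwise comparison 10 splits of the 6 arrays exist, too few for a share under 0.05. The real split called 225 genes for FSH against control and 67 for FSH+AEW against AEW, each 1 of 10 with as many, and the highest other split called 0. For AEW against control and FSH+AEW against FSH the real split called 0, and so did the others, 10 of 10. With the block, 4 splits part every pair, and 1 of the 4, the real one, called 1587, 374, 551 and 1226 genes for FSH against control, AEW against control, FSH+AEW against FSH and FSH+AEW against AEW, against 0 for the highest other. In every other split, with or without the block, a real difference between the groups would add to the spread and lower the count. The 0 of the other splits therefore gives little support to the real calls. For the interaction 100 permutations within replicate numbers were drawn, the real one included; 100 of 100 called at least the real 0, and the highest called 625, which points to a structure of the samples, since such permutations can turn the FSH effect into the interaction. For gene lists 4 of 100 permutations, the real one included, called at least the real 30 tests. The highest called 35, and the median among the others was 18, so relabelled arrays give many list calls at the preset correlation. The share is under 0.05, but barely and over few draws, and relabelled arrays can still carry the FSH effect. It therefore does not exclude chance, for single lists or for the count as a whole.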

How the results depend on the processing

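The blocked leave-one-out counts were added after seeing the data; all other alternatives were planned. No result reversed its direction where it had been called. The replicate block gave 1587 genes in place of 225 for FSH against control, 374 in place of 0 for AEW against control, 551 in place of 0 for FSH+AEW against FSH, and 1226 in place of 67 for FSH+AEW against AEW. As a random effect the number gave 1135, 77, 238 and 825, and array weights gave 724, 3, 1957 and 581. The block removes the spread between numbers, and for the array weights the cause was not tested. The block ended 1 of the 30 list calls, steroidogenesis in the interaction, and added cumulus expansion in both FSH comparisons and epithelial markers in FSH against control; it changed no other list call. A 2-fold threshold left 130 genes for FSH against control, and a fit on the 6 arrays of that comparison, with fewer arrays for the spread, left 12. Testing every probe set called 102 genes for FSH+AEW against AEW. Leaving out 1 array or 1 replicate number gave 4 to 222 genes for FSH against control, 0 to 1 for AEW against control, 0 to 16 for FSH+AEW against FSH, 2 to 119 for FSH+AEW against AEW and 0 for the interaction. Leaving out 1 array gave 26 to 32 list calls, and leaving out the third of genes with the lowest mean gave 25. For FSH against control the count was 74 without control replicate 1, 70 without control replicate 2, 46 without FSH replicate 3, 149 without AEW replicate 1, and 41, 97 and 4 without numbers 1, 2 and 3. For FSH+AEW against AEW it was 44 without control replicate 1, 41 without FSH replicate 3, 18, 7 and 3 without AEW replicates 1, 2 and 3, 119, 3 and 3 without FSH+AEW replicates 1, 2 and 3, and 26, 2 and 5 without the numbers. FSH+AEW against FSH had 3 genes without AEW replicate 1, 2 without FSH+AEW replicate 1, 1 without AEW replicate 3 and 16 without number 2, and AEW against control had 1 without number 2. With the block the ranges were 714 to 1705, 41 to 497, 130 to 623, 476 to 1446, and 0 to 9 for the interaction. Camera with a correlation estimated per list called 0 of 100 tests, with a smallest adjusted p of 0.0643. The retained share was 69.4% with 100 genes per selection, 79.3% with the block in the selection and 69.6% without the third of genes with the lowest mean, within the SD of 18.2. Median centring and repeated quantile normalization gave 192 and 248 genes for FSH against control and 61 and 100 for FSH+AEW against AEW. No background calls were used, so differences of dim genes such as FSHR have no stated limit.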

Other observations

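The contractile list was tested after a member's value had been seen, and the lists of this part were chosen after the main results; the predictions for the others were set before. Single genes named from these lists were chosen after their values were seen. Over 14 contractile genes and targets of serum response factor (SRF) outside the fixed list, the median was -0.75 ± 0.04 (SD of 3 numbers) in FSH against control and -0.58 ± 0.16 in FSH+AEW against AEW (camera adjusted p = 4.08e-12 and 1.25e-12 over 15 tests, and adjusted p = 0.0125 and 0.0125 with an estimated correlation). Alpha-actinin ACTN1 (-1.87), tropomyosin TPM2 (-1.58), caldesmon CALD1 (-1.29) and calponin CNN2 (-1.27) fell with FSH in limma's test. With the block 10 of 14 fell and 1 rose, FHL2 (0.42), while LMOD1 (0.27) did not pass; in FSH+AEW against AEW 9 fell and 0 rose. With AEW added to FSH the same list had a median of 0.25 ± 0.08 (camera adjusted p = 0.000458, a call lost at adjusted p = 0.162 with an estimated correlation), and 1 of 14 rose with the block. For AEW against control the median was 0.08 ± 0.09 (camera adjusted p = 0.0115, and adjusted p = 0.231 with an estimated correlation).

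Targets of YAP and TEAD, regulators that respond to cell tension, had a median of -0.47 ± 0.11 with FSH over 12 genes (camera adjusted p = 0.000458, and adjusted p = 0.231 with an estimated correlation), and 4 of them fell with the block. Their medians were -0.30 ± 0.20 in FSH+AEW against AEW and 0.23 ± 0.19 in FSH+AEW against FSH (camera adjusted p = 0.00639 and 0.0167, and adjusted p = 0.314 and 0.360 with an estimated correlation), where 4 fell and 1 rose with the block. HIF targets outside the fixed list lay higher with FSH, at 0.45 ± 0.26, and lower with AEW, at -0.34 ± 0.21, and their interaction was -0.47 ± 0.18 (camera adjusted p = 6.04e-05, 0.0115 and 0.000299, and adjusted p = 0.231, 0.360 and 0.231 with an estimated correlation). In FSH+AEW against FSH 6 of 15 fell with the block, such as RORA (-1.21), INSIG2 (-1.19) and ERO1A (-1.17).

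Contractile and matrix genes lower with FSH could reflect fewer stromal or theca-type cells or a change within cumulus cells. Over DCN, LUM, COL3A1, COL6A3, PDGFRA, TCF21 and COL15A1 the median was -0.66 ± 0.44 (SD of 3 numbers), against -0.67 for the fixed list. But 4 of the 7 belong to the fixed list, so the comparison is partly with itself and cannot tell the cell share from a change within cells. The theca list had a median of 0.02 ± 0.22, with 2 rises and 0 falls among 7 with the block. The epithelial list had a median of -0.16 ± 0.09, with 1 rise and 3 falls among 10. Camera called the epithelial list only with the block (adjusted p = 0.0379), a call lost at adjusted p = 0.319 with an estimated correlation. With the block DCN (-0.66), LUM (-0.99) and COL3A1 (-0.67) fell and COL15A1, dim at 3.34 in control, rose by 0.76, while PDGFRA (-0.82), TCF21 (-0.06) and COL6A3 (0.04) did not pass. The medians of -0.75 for the SRF list and -0.47 for the YAP list are consistent with less actin and tension signalling under FSH, as a hypothesis. Cell shape, density and cell counts were not measured here.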
